A study of Mus musculus and Homo sapiens with 83 samples.

How the data were processed

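The RRBS files give, per the submitters' processing notes and the file layout, the count of methylated calls and of all calls summed over the CpGs of each 100-bp tile; Trim Galore and Bismark 0.10.1 are named in the submitters' processing notes with genome builds mm9 and hg19. In 40 of the 54 RRBS files the authors also deposited a methylated fraction per tile, which differed from the ratio of calls by at most 5e-05, and the fraction was recomputed from the calls in all files. Of the RNA files, some hold values that are RPKM per the file headers and 1 gives RPKM per its file name only. Most of the others are headed FPKM per the file headers although the file names say RPKM, and the submitters' processing notes name TopHat and, for most of them, Cufflinks. Both units are length- and depth-scaled expression, so all are called RPKM in the text. Main comparisons were made between libraries of the same set, except 5-Aza-dC with DMSO, whose files differ in entries. The Dnmt3a transcript of MII oocytes with and without Dnmt3a, correlations of effects and the fit over all replicated mouse groups also cross sets. No counts of reads stand behind the RNA values, so count models were not used for RNA. For RRBS the counts of calls were used as deposited, and depth ranged from 20068567 to 289316638 calls per library.

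Groups were taken from the labels, and designs, tests, gene lists and most alternatives were chosen before the data were examined. A tile entered a comparison with at least 5 calls in every library. Library means are unweighted over those tiles and were compared by two-sided exact permutation. Tiles were tested with a quasi-binomial logistic model whose dispersion was moderated by limma squeezeVar with a floor of 1, and called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 points. RNA was tested by limma with a trend on log2 of RPKM + 1, over genes at RPKM 1 or more in at least 2 libraries of the fit, at an adjusted p under 0.05. Lists were tested by camera with a preset correlation of 0.01 and with an estimated correlation, and single-library lists were set against 10000 random lists matched in 20 bins of mean expression, over genes at RPKM 1 or more in 1 of the libraries. A single-library gene counted as changed at 4-fold or more on the RPKM + 1 scale, among genes at RPKM 5 or more in 1 of the libraries. The lists were methylation and chromatin regulators, 2-cell activated genes, early zygotic activation and nucleolar genes, oocyte and maternal-effect genes, germline genes silenced by methylation, imprinted genes, trophectoderm and inner cell mass regulators, p53 pathway genes, granulosa and cumulus markers, and other ovarian cell and blood markers. For HEK-293 the lists were cancer-testis and germline, imprinted, interferon-stimulated, methylation regulator and p53 pathway genes.

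The rule for naming was that each RNA comparison gives Dppa3 first, then Dnmt1, Dnmt3a, Dnmt3l, Uhrf1 and Tet3 (DPPA3, DNMT1, DNMT3A, DNMT3B and UHRF1 in HEK-293), then the 8 largest increases and 8 largest decreases. With replicates these had to pass the adjusted p with no overlap between groups, and with 1 library they had to reach RPKM 5. Predicted-gene and small RNA names were counted but passed over, and up to 4 members of a list were chosen by size of change. Named tiles are the 5 largest gains and 3 largest losses among called MII tiles with at least 20 calls in every library, and many tiles tie at the largest gain. Gene loci were taken from the coordinates in the RNA files, which carry no strand, so promoters were not analysed separately. Gene body values average all tiles of a locus, including those at its start, and needed at least 5 tiles. Dppa3 could not check the RRBS labels because the Stella-null libraries hold calls at that locus.

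The models were tested on simulated data of the same depths, after the first run of the tile tests. With 2 libraries per group, 0 of 2000 tiles raised by 40 points were called by the quasi-binomial model, edgeR or limma. With 3 per group the quasi-binomial model called 37.5% to 99.95% of raised tiles with under 4% false calls. Among unraised tiles up to 12.65% had a p under 0.05. The limma fits on RNA called 51% to 86.5% of 200 genes changed by log2 2. The alternatives were a depth of 10 calls, 30 points, limma on levels, weighting by depth, autosomes only, each library's own tiles, a pseudocount of 0.1, no filter, median-ratio rescaling, a fit over all replicated mouse RNA groups, the replicate number as a block, and leaving out each library. The edgeR quasi-likelihood test on calls, the set of tiles raised in both D20 comparisons, the permutation of backgrounds, the permutation of residuals with 100000 resamples, lists matched on the control library alone, list tests over genes expressed in the control side and over all genes, D5 groups counted as 1 sample each, the sum of 2-cell Stella-null replicates 1 and 3, and the application of the settings to named genes were chosen after seeing the data. R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with random seed 1.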

Results

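DNA methylation and gene expression were measured in mouse germ cells and early embryos that were heterozygous (Stella-het) or homozygous null (Stella-null) for Stella (Dppa3), a maternally supplied protein of oocytes and early embryos. Methylation was read by reduced-representation bisulfite sequencing (RRBS), which samples CpG-rich MspI fragments. Of the 83 libraries, 54 are RRBS and 29 are RNA sequencing. RRBS libraries numbered 3 per genotype for oocytes of postpartum day 5 (D5), for 2-cell embryos, and for mature metaphase II (MII) oocytes that also lacked Dnmt3a, Dnmt1 or Uhrf1. They numbered 2 per genotype for D10, D20 and MII oocytes and for the maternal and paternal pronuclei of zygotes 11 hours after fertilization. There was 1 library per genotype for male primordial germ cells of embryonic day 13.5 (E13.5) and for sperm. RNA libraries numbered 2 per group for MII oocytes, Dnmt3a-null MII oocytes, 2-cell embryos and each of the 4 groups of 2-cell embryos made by spindle transfer, and 1 per group for D5, D10 and D20 oocytes and for human HEK-293 embryonic kidney cells. An RRBS library held 20068567 to 289316638 CpG calls over 156021 to 894561 tiles of 100 bp, with a median of 27 to 426 calls per tile. The RNA files give no read counts, so the depth behind each expression value is unknown. The labels do not say that replicates are separate animals, so every p below measures only the spread between these libraries, which may be technical.

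The comparison of Stella-null with Stella-het oocytes from D5 to MII asked whether Stella limits methylation while the oocyte grows. Methylation was higher in Stella-null than in Stella-het oocytes at D5, D10 and MII, where every Stella-null library exceeded every Stella-het library. Over the tiles common to each comparison, mean methylation was 3.60% ± 0.00846 (SD, n = 3) in Stella-null and 2.43% ± 0.00960 (SD, n = 3) in Stella-het oocytes at D5, and 14.2% ± 0.839 (SD, n = 2) against 8.22% ± 0.238 (SD, n = 2) at D10. In MII oocytes it was 46.6% ± 3.36 (SD, n = 2) against 20.08% ± 2.56 (SD, n = 2), a difference of 26.6 points over 79764 tiles, and the same-numbered libraries differed by 27.1 and 26 points. At D20 the means were 42.4% ± 14.7 and 28.0% ± 8.67 (SD, n = 2 each), the groups overlapped, and the same-numbered libraries differed by 18.6 and 10.1 points. The D20 difference was 20.6 and 8.23 points without Stella-het replicates 1 and 2, and 3.91 and 24.7 points without Stella-null replicates 1 and 2. The two-sided exact permutation p was 0.1 at D5 and 0.333 at D10 and MII, the smallest these designs allow, and 0.667 at D20. It is unpaired, and in both genotypes D20 replicate 2 differed from replicate 1 in depth and mitochondrial level. The D20 SDs, p and values without a library therefore also measure that difference between the numbers.

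In MII oocytes 13365 tiles were higher and 210 were lower in Stella-null libraries, with a median gain of 87.9 points among the higher tiles. The 5 named gains went from 0% in both Stella-het to 100% in both Stella-null libraries. They lie in the Col19a1 locus, a collagen gene (mm9 chromosome 1, 24594200 to 24594299, at least 309 calls per library), at 137386400 to 137386499 (at least 342 calls) and 140687500 to 140687599 (at least 198 calls) on chromosome X, and at 152119900 to 152119999 (at least 28 calls) and 152099300 to 152099399 (at least 86 calls) on chromosome 4. The last 4 lie in no listed gene locus. The 3 named losses went from 100% to 0%, in the locus of Inhba, an inhibin and activin subunit (chromosome 13, 16109300 to 16109399, at least 96 calls), in the overlapping Dpcd and Fbxw4 loci (chromosome 19, 45682300 to 45682399, at least 70 calls) and outside gene loci on chromosome 17 (27178000 to 27178099, at least 48 calls). Adjusted p of the 8 tiles ran from 0.00498 to 0.00573 by the quasi-binomial test, and many other tiles tied with them at the full difference. In D5 oocytes 6162 tiles were higher and 2131 lower, and 3812 and 1274 at a difference of 30 points. At D10 and D20 the quasi-binomial test called 0 tiles, as did edgeR and limma, while 18731 higher and 2526 lower tiles at D10 and 81738 and 5189 at D20 passed an unadjusted p of 0.05 with 20 points. For MII, edgeR called 6 higher and 0 lower tiles and limma 12974 and 155, and without any single library of the 4 the quasi-binomial test called 0. Even with all 4 libraries it called 0 of 2000 tiles raised by 40 points in simulation, a smaller gain than the median of 87.9 points among called tiles. Designs with a library left out were not simulated. Whether low power alone explains the lack of calls in them thus cannot be told. The D5 libraries of a group agreed more closely than any other replicates, and whether they are independent samples is not known.

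**Figure D1:**
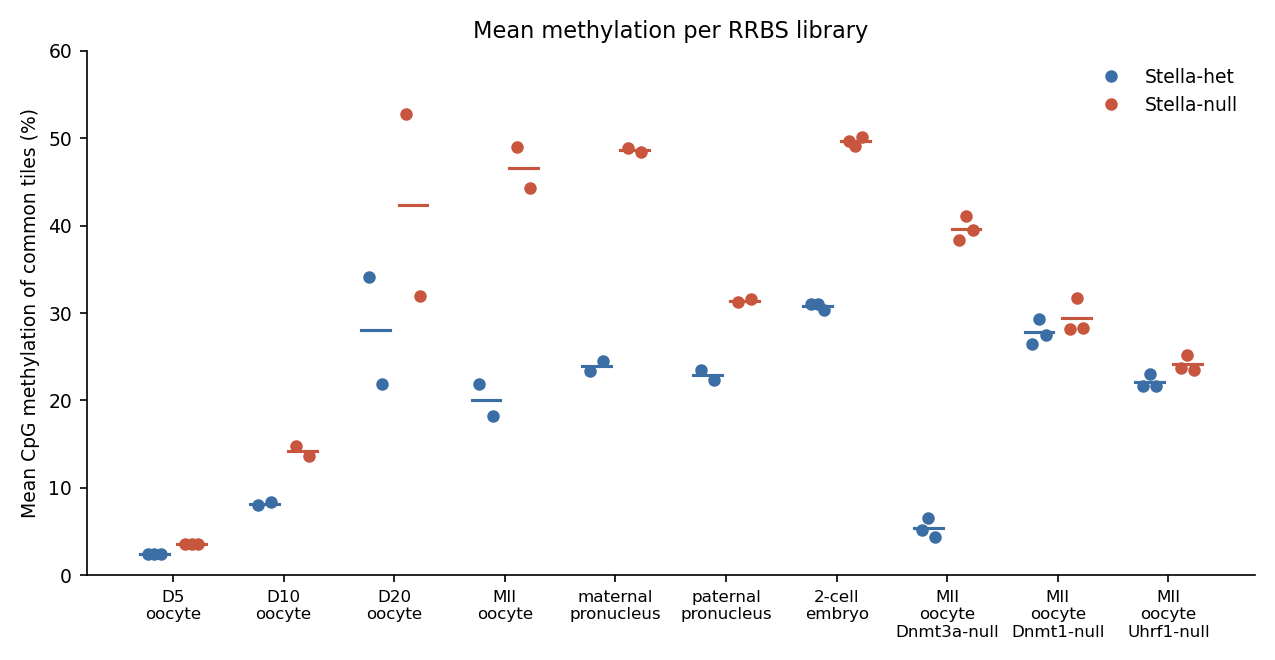
Mean CpG methylation in percent over tiles common to the libraries of each comparison; points are RRBS libraries and lines are group means. Stella-null MII libraries averaged 46.6% and Stella-het MII libraries 20.08%, while in the Uhrf1-null background the means were 24.2% and 22.1%. Tiles differ between comparisons, so levels are comparable only within one. Over shared tiles Stella-het means were 16.4% without Uhrf1 and 23.6% with it.

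The tiles that gained methylation in MII were followed to ask when the gain appears and whether it persists after fertilization. Of the 13365 tiles called higher in Stella-null MII oocytes, each stage covers those with at least 5 calls in all its libraries. Outside MII these numbered 8438 in paternal pronuclei to 13360 in E13.5 germ cells. They were nearly unmethylated in D5 oocytes of both genotypes, at 2.87% ± 0.0108 in Stella-null and 1.72% ± 0.00606 in Stella-het (SD, n = 3 each). In Stella-null oocytes they stood at 12.8% ± 0.527 at D10 and 42.1% ± 9.92 at D20, while Stella-het oocytes stood at 2.47% ± 0.0389 and 5.73% ± 1.40 (SD, n = 2 each). After fertilization they stood at 61.8% ± 2.02 in the maternal pronucleus, against 4.25% ± 0.159 in Stella-het (SD, n = 2 each), and at 50.0% ± 1.12 in 2-cell embryos, against 13.7% ± 0.371 (SD, n = 3 each). In the paternal pronucleus the covered tiles of this set differed by 8.58 points, in E13.5 male germ cells by 1.96 points and in sperm by -0.307 points. The two-sided exact permutation p was 0.333 for each stage with 2 libraries per genotype and 0.1 for D5 and the 2-cell embryo, the smallest these designs allow. The set was chosen on the MII libraries, so its MII levels of 82.2% and 3.70% carry no test.

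**Figure D2:**
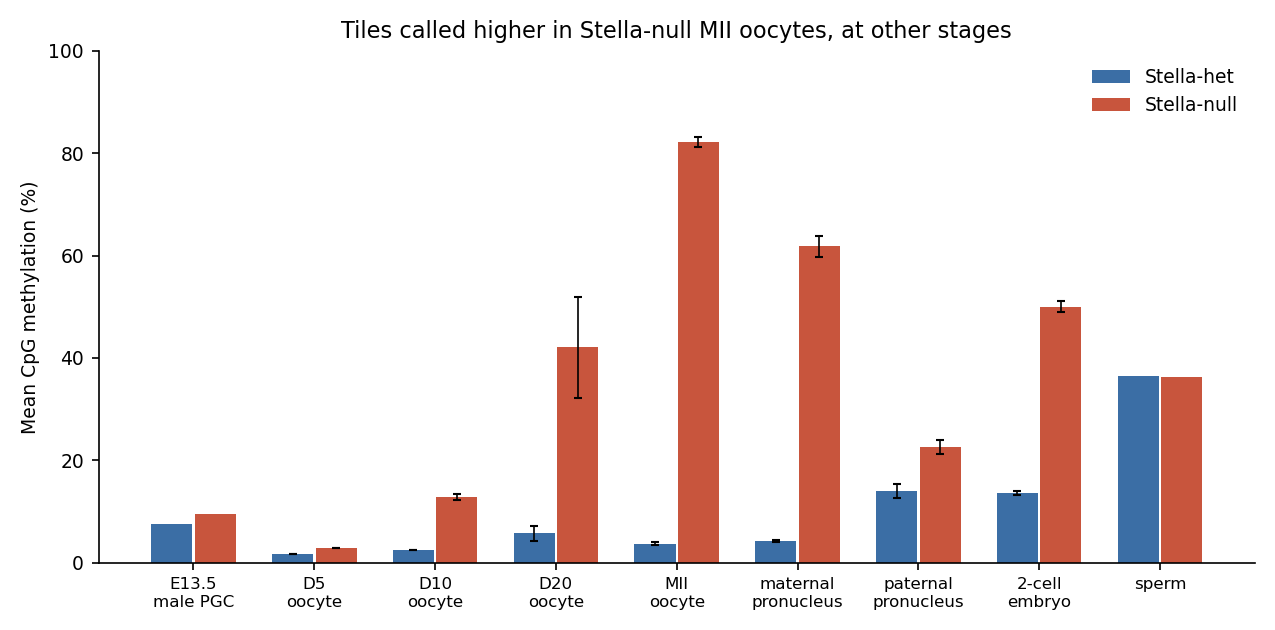
Mean CpG methylation in percent of the tiles called higher in Stella-null MII oocytes, at each stage over those covered in all its libraries. Bars are group means and lines 1 SD between libraries (no line where there is 1 library). Stella-null levels stood at 12.8% at D10, 42.1% at D20 and 82.2% at MII, where the tiles were chosen.

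Where the gain fell was compared between genes the oocyte expresses and the rest of the sampled genome. Among tiles under 20% in Stella-het maternal pronuclei, tiles in loci of genes at RPKM 1 or more in D20 oocytes gained least in Stella-null MII oocytes, by 10.4 points over 20508 tiles. Loci of other genes gained 52.8 points over 15335 tiles, and tiles outside gene loci gained 36.9 points over 20380 tiles. The same order held in maternal pronuclei (9.86, 46.2 and 37.3 points), whose Stella-het libraries defined the tiles, in 2-cell embryos (7.54, 30.4 and 25.6 points) and in Dnmt3a-null MII oocytes (10.3, 44.8 and 36.1 points). At D10 the gains were 1.31, 6.77 and 7.06 points, so expressed loci again gained least. Over whole gene loci, with tiles at their starts included, 303 of 2254 genes were at least 20 points higher in Stella-null MII oocytes. The gain was lower in genes with more transcript in Stella-het oocytes (Spearman rho -0.170 across genes, which are not independent replicates). This locus gain and expression change were hardly related, with rho 0.00719 in MII oocytes, 0.114 in Dnmt3a-null MII oocytes and -0.0853 in 2-cell embryos.

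**Figure D3:**
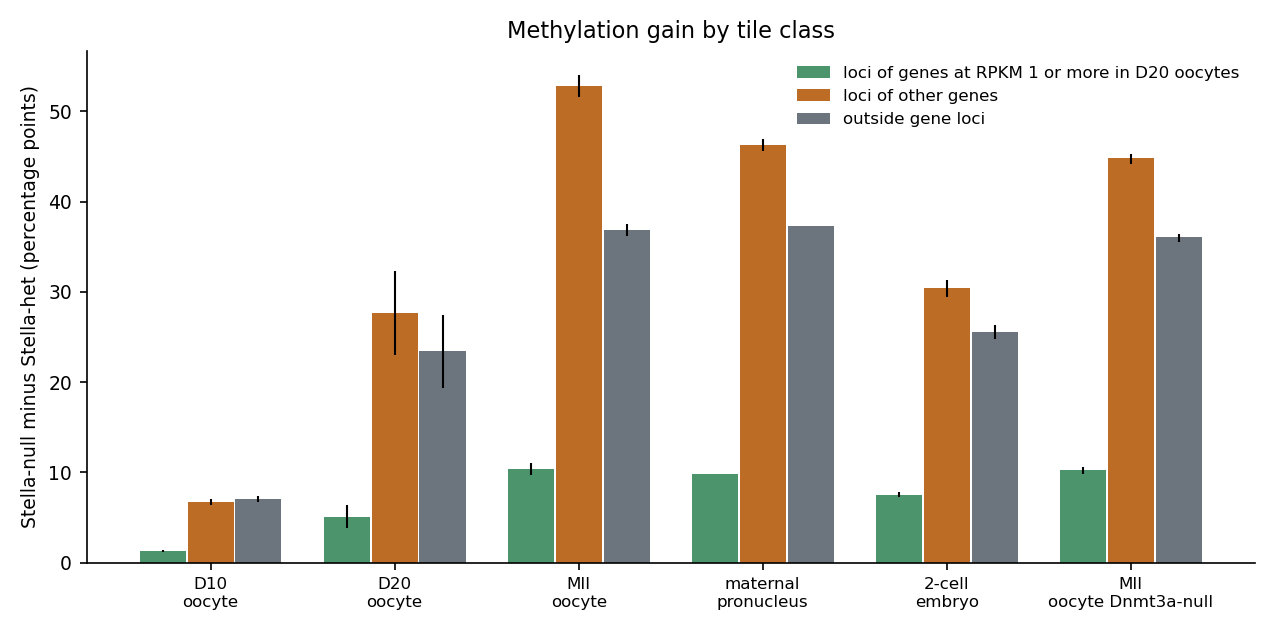
Stella-null minus Stella-het methylation in percentage points for 3 tile classes at 6 stages; bars are differences between group means and lines span the same-numbered library differences. Loci of genes expressed in D20 oocytes gained least at each stage, by 10.4 points in MII oocytes against 52.8 points in other gene loci.

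Zygotes and 2-cell embryos from Stella-null oocytes were compared with those from Stella-het oocytes to follow the maternal genome after fertilization. The maternal pronucleus carried 48.7% ± 0.288 methylation in Stella-null against 23.9% ± 0.825 in Stella-het zygotes (SD, n = 2 each), a difference of 24.8 points. The paternal pronucleus differed by 8.49 points, at 31.4% ± 0.210 against 22.9% ± 0.758 (SD, n = 2 each), and by 4.60 points with tiles weighted by depth. The 2-cell embryo carried 49.7% ± 0.515 against 30.8% ± 0.365 (SD, n = 3 each), a difference of 18.9 points. In maternal pronuclei 33674 tiles were higher and 514 lower, with a median gain of 74.8 points, and in 2-cell embryos 126963 were higher and 1170 lower, which is 36.3% and 0.335% of the tiles tested. Same-numbered libraries differed by 25.5 and 24.0 points in maternal pronuclei, 7.80 and 9.17 in paternal pronuclei, and 18.7, 18.1 and 19.8 in 2-cell embryos. The two-sided exact permutation p was 0.333, 0.333 and 0.1, the smallest each design allows. In paternal pronuclei the quasi-binomial test called 0 tiles, as did edgeR and limma, with 10571 higher and 875 lower at an unadjusted p of 0.05 and 20 points. The maternal calls did not persist without any single library, and the power of such designs was not simulated. With all libraries edgeR called 23222 higher and 79 lower tiles and limma 39058 and 775. The lower 2-cell count was 445 by edgeR, 425 at 30 points, 589 without Stella-null replicate 3 and 775 without Stella-null replicate 1.

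MII oocytes lacking Dnmt3a, the de novo methyltransferase of oocytes, Dnmt1, the maintenance methyltransferase, or Uhrf1, the cofactor that brings Dnmt1 to DNA, were compared to ask which of them the gain needs. Without Dnmt3a, Stella-het oocytes were almost free of methylation while Stella-null oocytes were not, at 5.39% ± 1.06 against 39.7% ± 1.36 (SD, n = 3 each), a difference of 34.3 points. Without Dnmt1 the Stella-null and Stella-het means were 29.4% ± 2.02 and 27.8% ± 1.41, and without Uhrf1 they were 24.2% ± 0.941 and 22.1% ± 0.782 (SD, n = 3 each), differences of 1.65 and 2.03 points. The Dnmt1-null difference was 0.866 and 2.70 points without Stella-het replicates 1 and 2 and 0.458 points without Stella-null replicate 2, and the Uhrf1-null difference was 0.946 points over each library's own tiles. The two-sided exact permutation p was 0.1 for Dnmt3a-null and Uhrf1-null oocytes, the smallest this design allows, and 0.4 for Dnmt1-null oocytes. It is unpaired, and same-numbered Dnmt1-null libraries differed by 1.72, 2.46 and 0.767 points, each higher in Stella-null. Of the 13365 tiles called higher in Stella-null MII oocytes, 10203 were covered without Dnmt3a, 11565 without Dnmt1 and 5284 without Uhrf1. Over these differing parts, Stella-null oocytes stood at 61.2% ± 1.09 without Dnmt3a, 13.3% ± 3.06 without Dnmt1 and 3.89% ± 1.44 without Uhrf1, against 2.98% ± 1.098, 4.47% ± 1.44 and 2.80% ± 0.957 in Stella-het (SD, n = 3 each). The two-sided exact permutation p on them was 0.1, 0.1 and 0.5. In Dnmt3a-null oocytes 127447 tiles were higher (55.8% of those tested, median gain 54.6 points) and 5 lower. In Dnmt1-null oocytes 4531 were higher and 3729 lower. In Uhrf1-null oocytes the quasi-binomial test called 0 tiles, as did edgeR and limma, with 4143 higher and 516 lower at an unadjusted p of 0.05 and 20 points. The lower Dnmt3a-null count was 1 by edgeR, by limma, at 30 points and without Stella-het replicate 1 or 2 or Stella-null replicate 3, and it was 17, 2 and 10 without Stella-het replicate 3, Stella-null replicate 1 and Stella-null replicate 2. The Dnmt1-null counts were 0 and 0 by edgeR, 800 and 1843 by limma, and 0 without any one of the 3 Stella-het libraries. Without Stella-null replicates 1, 2 and 3 in turn they were 2593, 1550 and 2132 higher and 1769, 1796 and 1629 lower.

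Against Stella-het MII oocytes with all of these genes, Stella-het oocytes without Dnmt3a were 19.5 points lower, falling from 23.2% ± 2.58 (SD, n = 2) to 3.68% ± 1.11 (SD, n = 3; two-sided exact permutation p = 0.1). Those without Uhrf1 were 7.27 points lower, at 16.4% ± 0.886 (SD, n = 3) against 23.6% ± 2.56 (SD, n = 2; exact permutation p = 0.1). Those without Dnmt1 were at 19.7% ± 1.38 (SD, n = 3) against 22.3% ± 2.57 (SD, n = 2; exact permutation p = 0.3), and the smallest p of each design was 0.1. The last difference, -2.61 points, was -0.862 and -4.40 points without MII Stella-het replicates 1 and 2. Over tiles common to all 4 groups, the Stella difference was 25.1 points in MII oocytes and 26.7 points without Dnmt3a, 26.2 against 0.825 points without Dnmt1, and 29.0 against 0.899 points without Uhrf1. The differences of these effects were -1.55, 25.4 and 28.1 points. The planned two-sided exact permutation of Stella labels within backgrounds gave p = 1, 0.267 and 0.3. It decides nothing here, because swapping the labels of all 4 MII libraries gives nearly the same absolute difference when the MII effect is this large, so its nominal smallest p of 0.0167 was out of reach. A two-sided exact permutation of background labels within genotypes, chosen after seeing the data, gave p = 0.8, 0.09 and 0.13 (nominal smallest 0.01). Where the effect lies in the Stella-null libraries, the 10 assignments of the Stella-het libraries give similar values, so p near 0.1 is about its lowest. An approximate permutation of the residuals of the additive model over all 10 libraries was added after both had failed to pass. This permutation gave p = 0.548, 1.4e-03 and 2.9e-04, with 5.5% of simulations without a difference under 0.05. By this test alone and over all common tiles, the Stella effect was smaller without Dnmt1 and without Uhrf1. For Dnmt3a the difference turned to 1.32 points with tiles weighted by depth, 6.34 points on tiles at least 20 points higher in both D20 comparisons, and 0.322 points without Stella-null MII replicate 2. It was -4.60 points without Stella-null MII replicate 1, -0.753 and -4.03 points without Stella-het MII replicates 1 and 2, and -2.38 and -0.904 points without Dnmt3a-null Stella-null replicates 1 and 2. On the D20 tiles, where the Stella difference was 75.4 points in MII and 69.0 without Dnmt3a, the permutation of residuals gave p = 0.0396. The Dnmt3a outcome of that test thus depends on the tile set.

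E13.5 male primordial germ cells and sperm were measured to see whether Stella acts before or outside oocyte growth. The Stella-null germ cell library averaged 13.8% against 10.9% in Stella-het, a difference of 2.82 points over 493654 tiles. The sperm libraries averaged 58.5% and 58.9%, a difference of -0.385 points over 455966 tiles. With 1 library per group neither difference can be set against replicate spread, and with tiles weighted by depth they were 1.71 and 4.72 points.

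RNA from growing oocytes was compared with 1 library per genotype, so no test applies. Dppa3 stood at RPKM 8114, 5916 and 4664 in Stella-het and 20.11, 25.9 and 14.7 in Stella-null oocytes at D5, D10 and D20. Among the methylation regulators, Dnmt1 stood at 519 in Stella-het and 363 in Stella-null oocytes at D5, Dnmt3a at 15.4 and 18.3, Dnmt3l at 18.1 and 18.0, Uhrf1 at 264 and 297, and Tet3 at 31.9 and 26.4. At D20, when Dnmt3l was highest in both genotypes, Dnmt1 was 356 and 312, Dnmt3a 15.6 and 21.8, Dnmt3l 114 and 133, Uhrf1 139 and 152, and Tet3 41.7 and 32.5; at D10, Dnmt1 was 508 and 444, Dnmt3a 14.0 and 16.7, Dnmt3l 55.7 and 44.2, Uhrf1 286 and 291, and Tet3 58.9 and 54.4. Genes normally switched on at the 2-cell stage were higher in Stella-null oocytes, with a median log2 difference of 1.09 over 9 measured genes at D5, 1.54 over 13 at D10 and 0.58 over 12 at D20. Each median exceeded those of all 10000 expression-matched random lists, although the Zscan4 and Usp17l members are close paralogs and not independent. Of the 43 listed genes, those silent in Stella-het oocytes are measured only if they rise, which favors high medians. Over all 31 genes in the tables, matched on the Stella-het library (chosen after seeing the data), the medians were 0.00, 0.15 and 0.05, at D10 above all random lists and at D20 above 99.38%, so the D5 increase depends on the filter. The 4, 5 and 8 genes at RPKM 1 or more in Stella-het oocytes had medians of -0.06, 0.22 and 0.20, above 55.32%, 91.62% and 96.49%. Zscan4d, a telomere-associated factor of 2-cell embryos, went from 0.283 to 4.00 at D5, 1.87 to 26.7 at D10 and 6.19 to 27.7 at D20. Usp17l5 went from 0.0532 to 3.14 at D5 and from 0.180 to 6.69 at D10. Pcp4, a calmodulin-binding peptide, went from 33.9 to 213 at D10 and 2.34 to 43.2 at D20, while Nhedc1, a sodium-proton exchanger, went from 22.8 to 1.35, Tmem47 from 7.91 to 0.953 and Tex15, a meiotic germline gene, from 21.7 to 3.56 at D20. Germline genes silenced by methylation had a median log2 difference of 0.20 at D5 and 0.28 at D10, above 99.99% and all of the random lists, and -0.16 at D20, above 8.41%; over all 34 in the tables they had 0.17 and 0.18 at D5 and D10, with the same ranks. Oocyte and maternal-effect genes had a median of -0.27 at D5, below all random lists, -0.02 at D10, above 0.15% of them, and 0.07 at D20, above 27.08%, with Bmp15 from 204 to 107 and Sohlh1 from 51.0 to 141 at D5.

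At a 4-fold difference, 23 genes were higher and 14 lower in the Stella-null library at D5, 41 and 24 at D10, and 28 and 17 at D20. Most of them carry predicted-gene or small RNA names, so the largest named changes given here include some under 4-fold. At D5 the named increases were Amd2 (log2 difference 3.71), Camk1g (2.06), Pdlim3 (1.73), Fbxo16 (1.70), Rhox1 (1.68), Snhg9 (1.65) and Elf3 (1.61), with Hist1h4a listed at 0 in Stella-het. The decreases below Dppa3 were Rps27 (-1.86), Insm1 (-1.56), Rpph1 (-1.47), Defb8 (-1.41), Sorcs3 (-1.38), Spry4 (-1.36) and Olfr206 (-1.36). At D10 Amd2 was again higher (2.88), with Cd1d1 (2.77), Aqp9 (2.36), Krt32 (2.32) and Lmx1a (2.22), and Gin1 (-3.64), Btg3 (-3.45), S100a16 (-2.30), Lyzl4 (-2.15), Hist1h2ba (-1.65) and Nfe2l2 (-1.63) were lower, with Rbp2 listed at 0 in Stella-null. At D20 Btg3 went the other way (3.16), and Slc4a3 (2.53), Reg2 (2.49), Glis1 (2.33), Mrap (2.23) and Fshr (2.13) were higher, while Prdx4 (-1.81), Cd200 (-1.75), Fam19a2 (-1.69) and Nmu (-1.68) were lower. Granulosa and cumulus markers, which would mark attached follicle cells, had medians of 0.55, 0.16 and -0.03 at D5, D10 and D20, above 99.8%, 88.69% and 60.33% of the random lists. Other ovarian cell and blood markers had medians of 0.75, 0.03 and 0.00, above 99.37%, 68.83% and 68.09%. The high D5 granulosa rank depends on genes under RPKM 1 in Stella-het oocytes: the 5 granulosa markers at RPKM 1 or more there had a median of -0.38, above 1.59% of random lists, while the 3 measured ovarian and blood markers, Krt8 (1.38), Pecam1 (0.75) and Cd68 (-0.10), were all at RPKM 1 or more there. The oocyte list also ranked low at D10, where neither marker list was extreme. The median log2 differences at D5, D10 and D20 were -0.09, -0.08 and -0.12 for methylation and chromatin regulators, -0.09, -0.03 and 0.01 for early zygotic and nucleolar genes, -0.05, 0.07 and 0.16 for imprinted genes, -0.01, -0.03 and -0.03 for p53 pathway genes, and 0.23, -0.08 and 0.03 for trophectoderm and inner cell mass regulators. Of these medians the trophectoderm list at D5 stood above 99.22% of random lists and the imprinted list at D20 above 98.64%, and the others above 6.68% to 83.62%. Over all listed genes in the tables, matched on the Stella-het library, the first was above 81.23% and the second above 56.59%, so both ranks depend on the filter.

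MII oocyte RNA was compared to ask what the loss of Stella does to the transcripts stored for the embryo. Dppa3 fell by 8.64 on the log2 scale (SE 0.495, limma adjusted p = 1.6e-04), from RPKM 5576 and 2459 in Stella-het to 13.9 and 4.77 in Stella-null oocytes. Nhedc1 fell by 2.86 (SE 0.296, limma adjusted p = 0.0159, lower in 2 of 2 libraries). The methylation regulators did not pass the test: the log2 difference was 0.57 for Dnmt1, 0.62 for Dnmt3a, 1.41 for Dnmt3l (limma adjusted p = 0.464), 0.34 for Uhrf1 and 0.07 for Tet3, with Dnmt3l at 11.0 and 24.4 in Stella-het and 34.2 and 60.0 in Stella-null. Of 8898 genes tested by limma, 0 were higher and 2 lower, with 279 higher and 392 lower at an unadjusted p of 0.05. That model leaves out the replicate number. Deviations of same-numbered libraries correlated by 0.498 here, and with the number as a block many more genes passed in both directions (counts below). The 2-cell activated list was higher as a set (camera adjusted p = 0.0279; adjusted p = 0.576 with an estimated correlation), with 0 of 7 measured members called over all genes and 3 adjusted over the list alone, among them Zscan4d at a log2 difference of 1.34. Other ovarian and blood markers were also higher as a set (camera adjusted p = 0.0394; adjusted p = 0.576 with an estimated correlation), with 3 measured members, of which 2, Kdr at 1.02 and Dcn at 0.92, passed when adjusted over the list alone. Both set results depend on the filter, because Dub1a, Zscan4c and Kdr had mean RPKM of 0.211, 0.386 and 0.701 in Stella-het and 1.63, 1.79 and 2.44 in Stella-null oocytes. Over genes at a mean of RPKM 1 or more in Stella-het oocytes (chosen after seeing the data), the 5 of 43 2-cell activated genes left did not pass (median -0.01, camera adjusted p = 0.311) and fewer than 3 ovarian markers were left. Over all genes neither list passed (camera adjusted p = 0.193 and 0.312). The remaining lists did not pass, with 1 higher imprinted gene (Cdkn1c, 1.45), 1 higher trophectoderm regulator (Klf4, 1.32) and 1 lower granulosa marker (Kitl, -1.10) when adjusted over the list alone, and 0 members of the methylation regulator, oocyte, early zygotic, germline and p53 lists either way. Without Stella-het replicates 1 and 2 and Stella-null replicates 1 and 2 in turn, 19, 45, 46 and 27 genes were higher and 11, 69, 90 and 15 lower, and with no filter 0 were lower.

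MII oocytes without Dnmt3a were compared in the same way to ask whether the RNA changes appear there too. Dppa3 fell by 8.51 on the log2 scale (SE 0.537, limma adjusted p = 1.3e-06), from RPKM 2861 and 1980 to 14.6 and 1.73. Nhedc1 again fell, by 3.14 (SE 0.270, adjusted p = 4.3e-05), and Tmem47 fell by 1.84 (SE 0.277, adjusted p = 0.0201), while Kera, a corneal keratan sulfate proteoglycan, rose by 1.83 (SE 0.280, adjusted p = 0.0201). The other lower gene was the predicted gene Gm19757, named after its value was seen. Dnmt3a transcript stood at 5.14 to 8.29 in these 4 libraries and at 13.8 to 31.2 in the other MII libraries, which belong to another set of files, and the log2 difference was 0.28 for Dnmt3a, 0.44 for Dnmt1, 1.19 for Dnmt3l (adjusted p = 0.103), 0.26 for Uhrf1 and 0.09 for Tet3, none past the test. Of 8979 genes tested by limma, 1 was higher and 4 lower, with 524 and 453 at an unadjusted p of 0.05. Across 8650 genes, which are not independent replicates, the Stella differences with and without Dnmt3a had a Spearman rho of 0.653. No list passed the set test (lowest camera adjusted p = 0.174, for early zygotic genes and granulosa markers), although over all genes without a filter early zygotic genes passed as higher (camera adjusted p = 0.0361); adjusted over the list alone, Dnmt3l passed in the methylation regulator and germline lists, 1 germline gene (Hormad1, -1.40) was lower and 1 ovarian marker (Dcn, 0.93) higher, and 0 members of the other 7 lists passed. Without Stella-het replicates 1 and 2 and Stella-null replicates 1 and 2 in turn, 39, 19, 5 and 297 genes were higher and 18, 12, 10 and 243 lower. With no filter 0 genes were called in either direction, and with the variance pooled over all replicated mouse groups 0 were higher and 2 lower.

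2-cell embryos from Stella-null oocytes and wild-type sperm were compared with those from Stella-het oocytes to ask how the maternal loss acts at genome activation. Dppa3 stood at RPKM 11785 and 8017 in embryos from Stella-het and 1704 and 879 in embryos from Stella-null oocytes, a log2 difference of -2.99 (SE 0.571) that narrowly missed the test (limma adjusted p = 0.0578). Kera rose most, by 3.31 (SE 0.284, adjusted p = 3.1e-04). Also higher were the calcium-binding protein gene Calb1 (2.27), the integrin gene Itgb6 (2.63), Apoo-ps (2.74), Tpbpb (2.23), Tcerg1l (2.11), the chemokine gene Ccl11 (1.95) and Cd69 (1.95). Lower were Klf5, a trophectoderm and inner cell mass regulator (-1.85), the growth factor gene Pdgfa (-2.56), Creb3 (-2.34), Ankrd33b (-2.20), Nup62cl (-1.90) and Zfp599 (-1.51). Dnmt1 (0.04), Dnmt3a (0.72), Dnmt3l (0.41), Uhrf1 (0.71) and Tet3 (0.95) did not pass the test. Of 11639 genes tested by limma, 14 were higher and 8 lower, with 790 and 615 at an unadjusted p of 0.05. Oocyte and maternal-effect genes were higher as a set (camera adjusted p = 0.00467; adjusted p = 0.957 with an estimated correlation) and early zygotic and nucleolar genes lower (camera adjusted p = 0.0411; adjusted p = 0.957 with an estimated correlation), with 0 members of either called over all genes or adjusted over the list alone. The list tests were repeated over genes at a mean of RPKM 1 or more in the Stella-het side, and over all genes, with the preset correlation only. The oocyte list passed (camera adjusted p = 8.8e-04 and 3.5e-07) and the early zygotic list did not (camera adjusted p = 0.120 and 0.448). Over all genes methylation regulators passed as higher (camera adjusted p = 0.0457). That setting takes in every gene above 0 in any library, and Stella-het replicate 2 lists far fewer genes at 0 (below). No repeat used an estimated correlation, with which the oocyte list did not pass. The 2-cell activated, methylation regulator, imprinted, germline, granulosa, ovarian and blood, and p53 lists had 0 members called either way, and Klf5 was the 1 member of the trophectoderm and inner cell mass list called both ways. The Stella-het replicate 2 library stood apart, with 1904 genes listed at 0 against 6639 to 6966 in the other 3, and without it 12 genes were higher and 9 lower. Without Stella-het replicate 1, Stella-null replicate 1 and Stella-null replicate 2 the counts were 305, 38 and 37 higher and 42, 66 and 32 lower. With the variance pooled over all replicated mouse groups 3 genes were higher and 4 lower, and with no filter 5 were lower. With the replicate number as a block many more genes passed in both directions (counts below).

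Spindle transfer exchanged the chromosomes and cytoplasm of wild-type (WT) and Stella-knockout (KO) oocytes, and RNA of the resulting 2-cell embryos was compared to ask whether the altered maternal chromosomes or the lack of cytoplasmic Stella changes expression. A KO cytoplasm changed many genes. Dppa3 itself fell by 2.53 on the log2 scale with KO cytoplasm (SE 0.270, limma adjusted p = 1.6e-03, n = 4 libraries per cytoplasm), from a mean RPKM of 8191 to 1376. Its spindle difference of 0.00 averages opposite directions: with KO cytoplasm it stood at 902 and 887 with KO and 1792 and 1923 with WT spindles, and with WT cytoplasm at 8308 and 13913 with KO and 4299 and 6243 with WT spindles (log2 differences -1.05 and 1.05, difference of the spindle effects -2.11, SE 0.541, limma adjusted p = 0.452). Of 13527 genes tested by limma, 678 were higher and 1165 lower with KO cytoplasm, with 1658 and 2433 at an unadjusted p of 0.05. Between KO and WT spindles limma called 0 genes, with 457 higher and 428 lower at an unadjusted p of 0.05, and the interaction of spindle and cytoplasm also gave 0, with 401 and 705. With the variance pooled over all replicated mouse groups, 21 and 45 genes passed for the spindle and 35 and 31 for the interaction, so an effect of the spindle is not excluded. The cytoplasm counts were 1615 and 2400 in that fit and 333 and 588 with no filter.

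With KO cytoplasm Uhrf1 rose by 1.56 (SE 0.201, adjusted p = 2.2e-03) and the dioxygenase gene Tet3 by 1.51 (SE 0.255, adjusted p = 5.6e-03), while Dnmt1 (0.47), Dnmt3a (0.64) and Dnmt3l (0.40) did not pass. Between spindles the log2 difference was 0.13 for Dnmt1, 0.00 for Dnmt3a, 0.35 for Dnmt3l, -0.35 for Uhrf1 and -0.35 for Tet3. The largest increases were Kera (3.64), Pcp4 (3.15), Calb1 (2.67), Nr2e3 (2.55), Plac1 (2.49), Lgi2 (2.43) and Krt71 (2.43), with the oocyte transcription factor gene Figla listed at 0 in all WT cytoplasm libraries and at a mean RPKM of 5.39 with KO cytoplasm. The largest named decreases were Ndufb7 (-3.40), Tmed4 (-3.17), Fam136a (-2.79), Trmt61b (-2.78), Timm13 (-2.67), the homeobox gene Hesx1 (-2.64) and Tomm5 (-2.62). Among oocyte and maternal-effect genes 11 of 33 measured rose and 0 fell (15 adjusted over the list alone; camera adjusted p = 1.6e-07; adjusted p = 0.0455 with an estimated correlation), including Zar1 (1.91), Nobox (1.71) and Ooep (1.54). Among early zygotic activation and nucleolar genes 11 of 35 fell and 0 rose (15 adjusted over the list alone; camera adjusted p = 2.9e-06; adjusted p = 0.0455 with an estimated correlation), including the ribosome biogenesis genes Wdr12 (-1.84), Bop1 (-1.48), Ddx21 (-1.38) and Gnl2 (-1.30). No other list passed the set test for cytoplasm. Of 27 methylation and chromatin regulators 4 rose and 3 fell (4 and 4 adjusted over the list alone), with Zfp57, which protects imprints, at 1.38 and Kdm5b at -1.09. Of 29 genes activated at the 2-cell stage 2 rose and 3 fell by both counts, with Zfp750 at 1.82 and Obox6 at -1.40.

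Of 33 germline genes silenced by methylation 1 rose and 4 fell with KO cytoplasm by both counts, with Taf7l at -1.92 and Tex19.1 at -1.19. Of 23 imprinted genes 2 rose and 2 fell by both counts, with Gnas at 1.31 and Phlda2 at -1.49. Of 22 trophectoderm and inner cell mass regulators Pou5f1 rose (0.98) and Klf5 fell (-0.88), and the counts adjusted over the list alone were also 1 and 1. Of 16 granulosa markers Fshr rose (1.45) and Nr5a2 fell (-1.26), 3 and 1 adjusted over the list alone, and 0 of 8 ovarian and blood markers and 0 of 21 p53 pathway genes changed by either count. Between spindles the oocyte list was higher as a set (camera adjusted p = 0.0461; adjusted p = 0.383 with an estimated correlation) with 0 members called by either count, and no other list passed. With the preset correlation only, the oocyte list again passed over genes at a mean of RPKM 1 or more with WT spindles (camera adjusted p = 0.0137). Over all genes early zygotic genes also passed, as lower (camera adjusted p = 0.0258). For the interaction no list passed, and adjusted over the list alone 1 germline gene was higher and 3 lower, with 1 and 1 among imprinted and among p53 genes. Across 11472 genes, the cytoplasm effect had a Spearman rho of 0.505 with the maternal Stella effect in unmanipulated 2-cell embryos, and the spindle effect 0.275; genes are not independent replicates. Leaving out libraries in turn, the cytoplasm counts were lowest at 220 higher without KO spindle, WT cytoplasm replicate 1 and at 375 lower without WT spindle, WT cytoplasm replicate 2. They were 253 and 514 without WT spindle, WT cytoplasm replicate 1, 243 higher without its replicate 2, 278 and 441 without KO spindle, WT cytoplasm replicate 2, 423 lower without its replicate 1, and 277 and 577 without KO spindle, KO cytoplasm replicate 1.

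HEK-293 cells overexpressing mouse Stella for 4 days, or treated with the demethylating drug 5-Aza-2'-deoxycytidine (5-Aza-dC), were compared with solvent-treated (DMSO) cells, with 1 library each and no test, to ask what Stella does in cells that lack it. The labels name no empty-vector control, so changes with Stella cannot be told apart from effects of the way it was introduced. The mouse transcript has no entry in the human tables, and human DPPA3 stood at RPKM 0.574 with DMSO, 0.880 with Stella and 0.414 with 5-Aza-dC. Cancer-testis and germline genes, which promoter methylation keeps silent in somatic cells, were higher under both treatments. With Stella 10 of 18 measured were at least 4-fold higher, with a median log2 difference of 2.02, and with 5-Aza-dC 20 of 27, with a median of 2.86, each above all 10000 random lists. Of the 40 listed genes 1 reached RPKM 1 with DMSO, so the others were measured only if they rose. Over all 37 genes in the tables, matched on the DMSO library (chosen after seeing the data), the medians were 0.58 and 2.07, again above all random lists. CTAG2 was listed at 0 with DMSO and stood at 88.9 with Stella and 25.1 with 5-Aza-dC, PAGE1 was listed at 0 and stood at 15.5 and 17.6, and DAZL was listed at 0 and stood at 23.2 with 5-Aza-dC. Imprinted genes had medians of 0.88 and 1.03, above 99.99% and 99.95% of random lists, or 0.45 and 0.20 over all 19 in the tables, above all and 98.11%, with MEST from 0.0198 to 3.58 and 10.2. Interferon-stimulated genes had a median of 0.52 with Stella, above all random lists, with BST2 from 1.19 to 16.5, and 0.36 with 5-Aza-dC, above 66.6% of them. Some interferon and imprinted genes were also measured only because they rose. Over all 24 interferon genes in the tables, matched on the DMSO library, the medians were 0.14 and 0.25, above 99.64% and 85.27%, and the 10 at RPKM 1 or more with DMSO had 0.28 with Stella, above 99.91%. The 6 imprinted genes at RPKM 1 or more with DMSO had 0.11 and -0.01, above 94.68% and 70.93%. Methylation regulators had medians of 0.00 and 0.72: DNMT1 stood at 47.6 with DMSO, 44.7 with Stella and 86.0 with 5-Aza-dC, DNMT3A at 2.56, 4.65 and 7.30, DNMT3B at 7.22, 8.74 and 12.0, and UHRF1 at 23.2, 22.9 and 42.5. The p53 pathway list had medians of 0.24, with CDKN1A from 23.5 to 70.2, and 0.26, with MDM2 from 3.47 to 18.0. With Stella and 5-Aza-dC in turn, the p53 medians were above all and 85.62% of random lists, and the regulator medians above 77.23% and 99.33%. Over all listed genes in the tables, the p53 list stood above all and 89.57%, and the regulators above 76.72% and 99.95%.

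At a 4-fold difference, 163 genes were higher and 76 lower with Stella, and 420 and 170 with 5-Aza-dC, or 366 and 254 after median-ratio rescaling. The largest increases with Stella after CTAG2 were the cytokine genes IL32 (log2 difference 5.78), CCL20 (5.06) and CCL2 (4.32) and the zinc finger gene ZCCHC12 (5.63), with GTSF1, PNMA5 and KRTAP19-5 listed at 0 with DMSO. The decreases included VTRNA1-3 (-1.99), LRRC26 (-1.70) and ETV4 (-1.66), with PTBP1, REV1, VTRNA1-2, SCARNA21 and SCARNA8 listed at 0 with Stella. With 5-Aza-dC the largest decreases were INO80B-WBP1 (-4.39), RPL21 (-4.32), TMEM160 (-3.80), LRRC26 (-3.43), RPS21 (-3.15), DDIT4 (-3.05) and HSPE1 (RPKM 728 to 90.4), with SCARNA23 listed at 0. The increases included the ribosomal protein pseudogenes RPSAP58 (7.36), RPS26P11 (7.08) and RPL13AP20 (6.72), with SLC25A6, SNAR-B1 and SNAR-B2 listed at 0 with DMSO. The 5-Aza-dC file was made differently, with 24940 entries against 23279, 392 duplicated symbols and a value total of 582766 against 884327, and rescaling moved its median log2 difference from -0.02 to -0.24, so its single-gene extremes are not comparable with those of Stella.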

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

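The test of incomplete conversion, and the tests by splitting the libraries of 2-cell embryos and of Dnmt3a-null, Dnmt1-null and Uhrf1-null MII oocytes, were chosen after the result was seen. Mitochondrial DNA, which the comparisons do not use, carried CpG calls in 52 RRBS libraries, of which 51 had the 1000 calls needed for a level, and the highest level was 3.88% in MII Stella-het replicate 1. The Stella-null mean exceeded the Stella-het mean by 0.00829 points in paternal pronuclei, 0.000572 points in 2-cell embryos and 0.0267 points in Uhrf1-null MII oocytes, and was lower in the other 7 comparisons.

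Incomplete conversion in Stella-null libraries was weighed as a technical cause of their higher methylation. Mitochondrial methylation was 1.53% in Stella-null and 2.02% in Stella-het MII oocytes and 0.187% and 0.986% in maternal pronuclei. Among comparisons with a tile difference over 5 points, the mitochondrial difference reached at most 0.0976% of the tile difference, in paternal pronuclei, which argues against this cause there. Mitochondrial methylation was also lower in Stella-null libraries at D5, at 0.0851% against 1.47%, and in Dnmt1-null oocytes, at 0.873% against 1.03%, and the Uhrf1-null excess of 0.0267 points compares with a tile difference of 2.03 points, which argues against this cause there too.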

How the results depend on the processing

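The edgeR test, the set of tiles raised in both D20 comparisons, the permutations of backgrounds and of residuals, control-matched lists, list tests with control-side or no filter, D5 groups counted as 1 sample each, the sum of 2-cell Stella-null replicates 1 and 3, and the application of the settings to named genes were chosen after seeing the data; the other settings were fixed before the data were examined. Counting D5 groups as 1 sample each leaves the D5 difference at 1.18 points by construction and allows no test. The sum of 2-cell Stella-null replicates 1 and 3 gave 118140 higher and 858 lower tiles. Over 94 results and 825 alternatives, 4 of 171 alternatives for means and differences of effects changed sign. Some of those 171, such as the replicate block and the added permutations, alter only the p and could not change it. For named genes 0 of 308 changed sign, while 21 of those 308 no longer passed the threshold. Named genes were chosen for no overlap between groups, so among their settings only rescaling could have changed a sign. Over all common tiles, the permutation of residuals passed for the differences of effects for Dnmt1 (25.4 points, p = 1.4e-03) and Uhrf1 (28.1 points, p = 2.9e-04), unlike the exact permutations. With tiles weighted by depth, the E13.5 germ cell difference was 1.71 points, the sperm difference 4.72 points and the Dnmt3a difference of effects 1.32 points. The last was 6.34 points on tiles raised in both D20 comparisons, where the permutation of residuals also passed (p = 0.0396). Tile counts (higher, then lower) with edgeR were 6 and 0 in MII, 0 and 0 in Dnmt1-null, and lower 79 in maternal pronuclei, 445 in 2-cell embryos and 1 in Dnmt3a-null oocytes. With limma on levels they were 800 and 1843 in Dnmt1-null, and lower 775 in maternal pronuclei and 1 in Dnmt3a-null oocytes. At 30 points they were 3812 and 1274 at D5, and lower 425 in 2-cell embryos and 1 in Dnmt3a-null oocytes. Gene counts with no filter were 333 and 588 for cytoplasm, 0 higher and 0 lower in Dnmt3a-null MII, and lower 0 in MII and 5 in 2-cell embryos. With the fit on all mouse groups they were 3 and 4 in 2-cell embryos, 0 and 2 in Dnmt3a-null MII, 21 and 45 for the spindle, 1615 and 2400 for cytoplasm, and 35 and 31 for the interaction. With an estimated correlation 2 lists passed instead of 7. With the preset correlation, 4 passed with the filter on the control side and 7 with no filter, not all the same lists. Neither MII list passed in these alternatives.

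The labels do not say that replicate numbers pair the libraries, and deviations of same-numbered libraries correlated by at most 0.0536 over tiles with 3 pairs. With only 2 pairs the correlation was 0.437 for D20 tiles, 0.498 for MII RNA and 0.320 for Dnmt3a-null RNA. These correlations cannot show a shift shared by a whole library. The order of library means followed the number in both genotypes at D5, D20 and MII and in Dnmt1-null and Uhrf1-null oocytes. It did so only in part in Dnmt3a-null oocytes, and not at D10, in pronuclei or in 2-cell embryos. The unpaired exact permutations leave such pairing out. Mitochondrial methylation followed the number across genotypes at D20 (2.75% and 2.63% in replicate 1, 0.193% and 0.206% in replicate 2), in MII oocytes, 2-cell embryos and Dnmt3a-null, Dnmt1-null and Uhrf1-null oocytes, but not in maternal pronuclei, so shared handling of same-numbered libraries is not excluded. With the replicate block the tile counts were 4791 and 52 in MII, 0 and 0 in maternal pronuclei and in Dnmt1-null oocytes, and lower 760 in 2-cell embryos and 0 in Dnmt3a-null oocytes. Gene counts with the replicate block were 299 and 431 in MII, 190 and 142 in 2-cell embryos and 4 higher in Dnmt3a-null MII.

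Leaving out 1 library, lowest to highest, tile counts were 0 to 0 higher and 0 to 0 lower in MII and in maternal pronuclei, 0 to 2593 and 0 to 1796 in Dnmt1-null, and lower 589 to 1592 in 2-cell embryos and 1 to 17 in Dnmt3a-null oocytes. Gene counts were 19 to 46 and 11 to 90 in MII, 5 to 297 and 10 to 243 in Dnmt3a-null MII, 12 to 305 and 9 to 66 in 2-cell embryos, 220 to 878 and 375 to 1406 for cytoplasm, and lower 0 to 1 for the spindle and for the interaction. The Dnmt3a difference of effects ran from -4.60 to 0.322 points, the latter without MII Stella-null replicate 2. A lone library was assumed to vary like the other group.

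The counts in designs of 2 against 2 depend on the test, and the cause was not tested. Promoter methylation and its alternative with a shorter distance were not run because gene loci carry no strand. In 7 comparisons the deposited tiles already held at least 10 calls, so the depth of 10 tested nothing there. The planned set of tiles called at D20 was empty and could not be followed.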

Other observations

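The tests by splitting the libraries of 2-cell embryos and of Dnmt3a-null, Dnmt1-null and Uhrf1-null MII oocytes were chosen after the result was seen. The set of tiles at least 20 points higher in both D20 comparisons holds 96332 tiles. Each group below covers a part of it, from 15560 tiles in MII oocytes to 89690 in sperm. Over these differing parts, the Stella difference was 75.4 points in MII oocytes, 66.6 in maternal pronuclei, 42.5 in 2-cell embryos, 69.2 without Dnmt3a, 13.0 without Dnmt1, 2.31 without Uhrf1 and -0.340 in sperm. Among tiles under 20% in Stella-het maternal pronuclei, gains in the paternal pronucleus were 2.34 points in loci expressed in D20 oocytes, 8.87 in other gene loci and 8.35 outside gene loci.

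The gain in MII oocytes was weighed against gene expression with a bound set before the result was seen. The gain outside gene loci exceeded that in expressed loci by 26.5 points in both same-numbered comparisons, over a bound of 10 points. Expressed loci may gain less because of transcription, or because their tiles differ in CpG density, and no value here parts these.

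Cytoplasm and spindle were weighed as the source of the expression changes in transferred embryos. Across genes the cytoplasm effect had a rho of 0.505 with the maternal Stella effect and the spindle effect 0.275. The splits used a fit of 2 groups that leaves out the other factor, unlike the fit behind the counts of 678 and 1165 genes. Among the 35 splits of the 8 libraries into 4 and 4, the cytoplasm split called 1670 genes and the highest other 2. A share of 1 in 35 is under 0.05 but is the smallest possible here. Chance is thus unlikely for the cytoplasm, if the libraries are independent, but not excluded. For the spindle the same fit leaves the cytoplasm effect in the residual, and 35 of 35 splits call at least its 0 whatever the data, the highest other, 1670, being the cytoplasm split, so it decides nothing about the spindle.

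With 6 libraries there are 10 splits, too few for a share under 0.05. The real split called 8293 tiles at D5, 128133 in 2-cell embryos, 127452 in Dnmt3a-null and 8260 in Dnmt1-null oocytes, with a highest other of 0 in each and 1 split of 10 as large. In Uhrf1-null oocytes it called 0, and 10 of 10 splits did.

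The D5 libraries of a group could be repeat runs of 1 library. The variance of calls per tile over their mean was 3.36 to 3.57 between them and at least 8.08 between other replicates, a ratio of 0.442, between the bounds set beforehand, so repeat runs and separate samples cannot be told apart.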
